A study of Mus musculus with 8 samples.

How the data were processed

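RNA-seq was carried out on 8 libraries of mouse esophageal organoids. Esophageal cells of wild-type mice were grown in a basement membrane gel for 13 days with medium changes every 2 days, and treated for 72 h with renewal every 24 h, per the labels' protocols. Libraries were made with the Ovation SoLo kit and sequenced on an Illumina NovaSeq, per the labels' protocols. The groups of 2 libraries were inhibitor, BMP4 with inhibitor, TGFb1, and TGFb1 with BMP4.

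STAR 2.5.3a, HTSeq, edgeR, Cell Ranger 3.1.0 and the builds GRCm38 and mm10 are named in the submitters' processing notes, with no roles or order. The annotation, the filters and the strand setting of the counting are not given in the sources used here. The deposited whole-number values are a score, namely read counts that were scaled to about 20000000 per library and rounded up. This was read from the values, since each library summed to 20000000 plus about 0.5 per gene above 0. The deposited CPM values equalled these values divided by their column totals, to within 0.0005. The deposited log2 fold changes and the deposited p-values and FDR, with 1 test per gene over all groups, were the authors' own, and were used only for comparison. The authors' deposited table listed 52636 genes, of which 4629 had an FDR under 0.05, and the lowest FDR was 0.000761. Across tested genes the log2 fold changes of the authors' deposited table and those computed here had correlations of 0.942 for TGFb1, 0.928 for BMP4 with inhibitor and 0.946 for TGFb1 with BMP4. A second sheet held the same values to a relative difference of 7.5e-11 and was not used here.

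The planned count test was replaced because the deposited values were scaled, and limma was used instead. Reads per library inferred from the pattern of low values lay between 28600000 and 43600000. These reads are an estimate and entered no comparison of groups. The 10 most abundant genes held 3.36 to 4.69% of each library. Of 52636 genes, 20292 were at 0 in every library. Counting floors cover counting error only, and rounding up raises the lowest values, so genes near 0.15 CPM are imprecise. Gene positions came from GENCODE mouse release M21 on GRCm38, to which 52489 gene IDs (99.72%) matched. Overlapping, antisense and near-identical genes may share reads.

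Genes at 1 CPM or more in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (trend, log2(CPM + 1), two-sided). All 8 libraries entered with group as the only term, which left 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each of 6 comparisons, with a threshold of 0.05. Fold changes on this scale understate the change of low genes. In simulated data for TGFb1 against inhibitor with 14874 genes tested, 69 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were called, with 9 of 14674 unchanged genes. The simulated libraries were independent, with the same dispersion of 0.03 for every gene, 200 changed genes and no effect of the replicate number. These rates may therefore not hold for the real libraries.

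Gene lists, 30 in number and holding 642 genes, of which 639 were in the table and 534 were tested, were fixed before the data were examined. The 28 lists with 5 or more tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted within each comparison. With an estimated correlation 0 of the 69 list calls held. The mean, the median and the test of each called list had the same sign. A count "adjusted over the list alone" applies the Benjamini-Hochberg method to the list's own members.

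The rule for named genes was also fixed before the data were examined. It took the 5 largest and 5 smallest called log2 fold changes per comparison among genes at 5 CPM or more in the higher group whose libraries did not overlap, leaving out predicted genes. For the interaction it took genes at 5 CPM or more in any group and did not ask that libraries be apart. For the other comparisons it added up to 3 called members per list by smallest adjusted p, and 20 genes fixed by name. Some genes that the rule takes are counted but not reported here.

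Replicate numbers came from the labels, which do not say what they share. Deviations from the group means correlated between same-numbered libraries by 0.6, 0.32, 0.38, 0.49, 0.52 and 0.74 in the 6 pairs of groups, all over 0.1, so a fit with the replicate number as a block is given where it changes a call. Replicates were distinct libraries, with a chi-square per gene between 48.1 and 143.9.

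Alternatives were a minimum log2 fold change of 1, median-of-ratios scaling, no filter, a stricter filter of 1 CPM in 4 libraries, the replicate block, a fit of the compared groups alone, a pseudocount of 0.1, each library left out, and fry or an estimated correlation for lists. Fits with a library left out held no replicate block, so the replicate numbers were then unequal between groups. Voom weights, the block with median-of-ratios scaling, the mean level of muscle markers as a covariate and the block for the overlaps of calls were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.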

Results

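RNA was sequenced from mouse esophageal organoids, which are 3-dimensional cultures of esophageal epithelial cells grown in a basement membrane gel. The 8 libraries formed 4 groups of 2. Control organoids received A8301, a small-molecule inhibitor of TGFb type I receptors, at 500 nM. Another group received the inhibitor with BMP4 at 20 ng/ml, another received TGFb1 at 1 ng/ml, and the last received TGFb1 with BMP4 at these doses. Treatment lasted 72 h and was renewed every 24 h. The labels list no inhibitor for the TGFb1 groups, so each comparison of a TGFb1 group with an inhibitor group covers both the added ligand and the absent inhibitor. The same holds for the interaction of BMP4 with TGFb1. Nothing in the labels says that the 2 libraries of a group came from separate animals, so p-values of single genes measure the spread between these libraries. List p-values from camera instead compare the members of a list with other genes, at a preset inter-gene correlation of 0.01.

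The deposited values were read counts scaled to about 20000000 per library, and their totals lay between 20011215 and 20013233. The read depth inferred from the spacing of the values lay between 28600000 and 43600000 reads in genes. Between 23718 and 27476 genes were above 0 in a library. At these totals 3 units equal 0.15 CPM, the value per library total used here. A read made between 0.459 and 0.7005 units by inference. After rounding up, 0.15 CPM therefore lies at or above the 3 reads that a 0 allows, for counting error only. Of 52636 genes, 16180 reached 1 CPM in at least 2 libraries and were tested. Errors beside CPM are SD with n = 2, and errors beside a log2 fold change, taken on log2(CPM + 1), are SE from limma. The first principal component held 68.1% of the variance and parted the libraries with TGFb1 from those without it.

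The first comparison asked what BMP4 did while TGFb signalling was inhibited. BMP4 raised its known feedback and target genes. Smad6, an inhibitory SMAD of the BMP pathway (ENSMUSG00000036867, chromosome 9, 63953076 to 64022059, GRCm38), went from 3.37 ± 0.389 to 22.1 ± 8.02 CPM, a log2 fold change of 2.36 ± 0.25 (adjusted p = 0.00503). Id3, a transcriptional regulator induced by BMP (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755), went from 54.0 ± 17.4 to 265 ± 31.5 CPM (2.31 ± 0.33, adjusted p = 0.0122). Smad7 went from 23.8 ± 4.49 to 68.9 ± 10.8 CPM (adjusted p = 0.0109). Nog, which encodes the BMP antagonist noggin, rose by 3.84 ± 0.34 (adjusted p = 0.00357), and Bambi, which encodes a pseudoreceptor, by 3.63 ± 0.23 (adjusted p = 0.00183). Id1 was at 86.9 ± 2.23 and 225 ± 8.37 CPM and missed the threshold (adjusted p = 0.0562), which it passed with a replicate block (adjusted p = 0.0307). Of 18 tested BMP response genes, 10 rose and 0 fell, with 15 rising when adjusted over the list alone, and the list test gave an adjusted p = 7.19e-10 (adjusted p = 0.211 with an estimated correlation).

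BMP4 also changed keratins and other genes of the squamous epithelium. Krt4, a keratin of differentiated esophageal cells (ENSMUSG00000059668, chromosome 15, 101918535 to 101924735), fell from 3460 ± 900 to 453 ± 130 CPM, a log2 fold change of -2.94 ± 0.31 (adjusted p = 0.00499). Its partner Krt13 fell by 0.86 on the log2 scale (adjusted p = 0.0406, 0.0539 with median-of-ratios scaling, and 0.0641 to 0.205 with each library left out), and Krt15 went from 372 ± 23.9 to 23.5 ± 4.91 CPM (adjusted p = 0.000727). Krt10, a keratin of the suprabasal epidermis (ENSMUSG00000019761, chromosome 11, 99385254 to 99389364), rose from 7.20 ± 5.72 to 803 ± 218 CPM (6.79 ± 0.53, adjusted p = 0.00219). The largest rise was that of Tgm7, a transglutaminase gene (chromosome 2, 121093565 to 121109795), from 0.850 ± 0.565 to 692 ± 167 CPM (8.56 ± 0.35, adjusted p = 0.000727). Frem2 (6.01 ± 0.45), Lgr6 (5.96 ± 0.74) and Stmn2 (5.96 ± 0.36) were the other genes among the 5 largest rises, and Lgr6 was at 159 and 27.1 CPM in the BMP4 libraries. The largest falls were those of Serpinb12 (-6.20 ± 0.67), Cyp2b10 (-4.45 ± 0.44), Inpp4b (-4.45 ± 0.72), the chemokine gene Ccl20 (-4.43 ± 0.29) and Krt15 (-3.94 ± 0.16). Basal and suprabasal lists moved in both directions. Of 22 basal genes, 7 rose and 2 fell, and the list's adjusted p was 0.0434 (0.0631 with the replicate block, and adjusted p = 0.694 with an estimated correlation). That call was also lost without inhibitor replicate 1 (adjusted p = 0.0825) or BMP4 + inhibitor replicate 2 (adjusted p = 0.129). Of 38 suprabasal genes, 4 rose and 4 fell (list adjusted p = 0.431).

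Genes known as TGFb targets rose with BMP4 although the inhibitor was present. Of 24 tested TGFb response genes, 11 rose and 0 fell (12 adjusted over the list alone), with a median log2 fold change of 1.32 and a list adjusted p = 1.01e-08 (adjusted p = 0.177 with an estimated correlation). Itgb6, an integrin subunit that activates TGFb, rose from 53.4 ± 1.20 to 262 ± 22.9 CPM (adjusted p = 0.00136). Tgfbi rose by 2.70 ± 0.21 (adjusted p = 0.00219), and Cdkn2b, a CDK inhibitor gene, by 2.16 ± 0.21 (adjusted p = 0.0045). The simple-epithelium keratin Krt7 rose from 16.8 ± 3.25 to 134 ± 77.3 CPM (adjusted p = 0.0109). Of 14 tested columnar genes, from a list of 32, 4 rose and 0 fell (list adjusted p = 0.00998, and adjusted p = 0.694 with an estimated correlation). Of 33 extracellular matrix genes 6 rose and 0 fell, and 28 rose and 1 fell with the replicate block (list adjusted p = 7.68e-06, and adjusted p = 0.721 with an estimated correlation). Summed muscle markers were at 59.0 ± 56.1 CPM in the control and 190 ± 163 CPM with BMP4, and the muscle and fibroblast lists passed with the block but not without it (adjusted p = 5.49e-05 and 0.00166, against 0.129 and 0.133). Summed fibroblast markers were at 556 ± 134 and 919 ± 268 CPM. Only 14 of the 17 fibroblast markers lie outside the matrix list, so their sum and list also count matrix genes in every comparison.

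Glycolysis and hypoxia genes fell. Of 24 members 7 fell and 0 rose (15 fell and 1 rose adjusted over the list alone), with a list adjusted p = 3e-06 (adjusted p = 0.694 with an estimated correlation). Car9, a carbonic anhydrase gene induced by hypoxia, went from 29.6 ± 17.2 to 2.32 ± 1.02 CPM (adjusted p = 0.0186). Ribosomal protein genes had a median of -0.44, and 0 of 30 passed singly (list adjusted p = 6.92e-05, adjusted p = 0.721 with an estimated correlation), while 17 fell with the replicate block. All 30 were higher in replicate 2 (median log2 ratio 0.39), as were 8 of 8 mitochondrial transcripts (0.49). Mitochondrial transcripts held 0.414% of BMP4 + inhibitor replicate 1 and 0.655% of replicate 2, against 0.657% and 0.684% in the control libraries. The ribosomal list call was lost without BMP4 + inhibitor replicate 1 (adjusted p = 0.0879). Krt5, Trp63, Sox2, Krt18, Sox9, Mki67, Cdkn1a and Cdh1 did not pass. Krt14 and Vim passed with the block but not without it (adjusted p = 0.022 and 0.00347, against 0.0775 and 0.236).

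Of 28 lists, 10 passed, against 6 with fry, which lost 5 of the 10, namely the matrix, ribosomal, EMT, Wnt and cholesterol synthesis lists (adjusted p = 0.138, 0.372, 0.248, 0.0885 and 0.138). The EMT, Wnt and cholesterol synthesis calls were also each lost without inhibitor replicate 1 or BMP4 + inhibitor replicate 2. In all, limma called 889 genes higher and 471 lower with BMP4 under inhibition. With the replicate block it called 1909 higher and 1593 lower, and all 1360 calls remained in the same direction. It called 1978 and 2139 with the muscle marker level as a covariate, 509 and 242 with no filter and 400 and 181 on the compared groups alone. Of 65 named calls, 27 held with each library left out, among them Smad6, Nog, Bambi, Itgb6, Tgfbi, Cdkn2b, Krt4, Krt15, Krt10, Tgm7, Frem2, Stmn2, Serpinb12, Cyp2b10 and Ccl20, while Id3, Smad7, Krt7, Lgr6, Inpp4b and Car9 lost theirs in at least 1 case. The named calls lost numbered 34 without inhibitor replicate 1, 35 without inhibitor replicate 2, 32 without BMP4 + inhibitor replicate 1 and 4 without BMP4 + inhibitor replicate 2. The total was 271 without inhibitor replicate 1, 188 without inhibitor replicate 2, 333 without BMP4 + inhibitor replicate 1 and 2300 without BMP4 + inhibitor replicate 2.

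**Figure D1:**
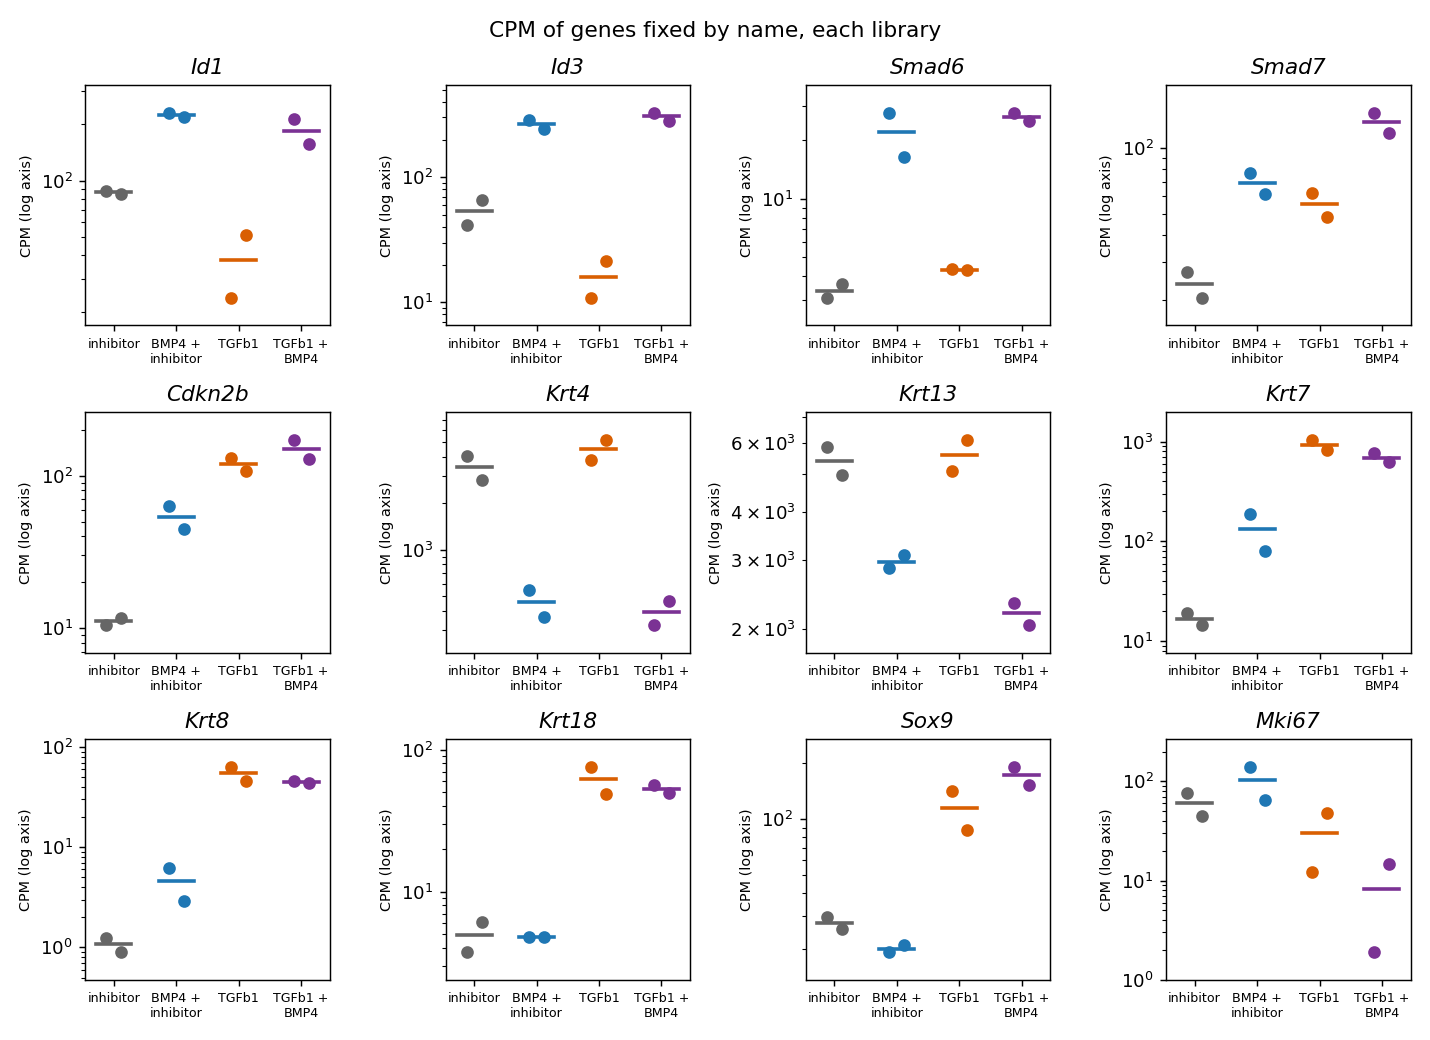
CPM (log axis) of 12 genes in each of the 8 libraries, by group, with points for libraries and bars for group means. Krt4 sits at 453 and 391 CPM on average in the groups with BMP4 against 3460 and 4535 CPM in those without it, and Krt7 is at 935 and 695 CPM in the groups with TGFb1.

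The next comparison set TGFb1 against the inhibitor. TGFb1 raised its known targets and the keratins of simple epithelium. Of 24 TGFb response genes, 21 rose and 0 fell (22 adjusted over the list alone), with a median of 3.28 and a list adjusted p = 7.55e-11 (adjusted p = 0.112 with an estimated correlation). Pmepa1 rose by 5.13 ± 0.24, Ldlrad4 by 3.76 ± 0.17 and Cdkn2b by 3.31 ± 0.21 (adjusted p = 0.000118, 0.000114 and 0.000284). Id1 and Id3 fell by 1.28 and 1.72 on the log2 scale (adjusted p = 0.0241 and 0.00849). Krt7 (ENSMUSG00000023039, chromosome 15, 101411043 to 101430313) rose from 16.8 ± 3.25 to 935 ± 157 CPM (5.72 ± 0.39, adjusted p = 0.000319). Krt8 rose by 4.73 ± 0.31, Krt18 by 3.41 ± 0.26, Krt19 by 6.14 ± 0.36 and Krt20 by 7.26 ± 0.22, and Sox9, a transcription factor of columnar and progenitor cells, went from 27.7 ± 3.00 to 114 ± 38.5 CPM (adjusted p = 0.00179). Of 14 tested columnar genes 10 rose and 1 fell (list adjusted p = 4.57e-05, adjusted p = 0.642 with an estimated correlation). The other members of this list of 32 were too low to be tested in any comparison. Among them Hnf4a reached at most 0.1 CPM and Gata4 0.3 CPM in any library, and the highest, Tspan8, reached 3.65 CPM. The basal keratin Krt14 rose by 0.60 ± 0.20 (adjusted p = 0.0486), but did not pass with median-of-ratios scaling (adjusted p = 0.0741) or a stricter filter (adjusted p = 0.0548), nor with any 1 library left out (adjusted p = 0.116 to 0.21). Trp63, which encodes a basal cell regulator, fell by 0.97 on the log2 scale (adjusted p = 0.00162), and Krt4 and Krt13 did not pass (adjusted p = 0.325 and 0.851). Krt5 and Cdh1 passed with the replicate block but not without it (adjusted p = 0.0339 and 0.0264).

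The largest rises were those of Alox15, a lipoxygenase gene (1.97 ± 0.813 to 888 ± 60.3 CPM), the elastin gene Eln (8.01 ± 0.85), Adam12, a metalloprotease gene (7.69 ± 0.14), the chemokine gene Ppbp (7.66 ± 0.24) and Krt20. The largest falls were those of Serpinb12 (-7.14 on the log2 scale), Smpd3 (-6.60), Aloxe3 (-6.53), Rptn (-6.33) and Lce1d (-6.29). Rptn, which encodes repetin, was at 3.90 and 322 CPM in the 2 TGFb1 libraries, against 3239 ± 589 CPM in the control. Of 38 suprabasal genes 17 fell and 7 rose, and the list did not pass (adjusted p = 0.0807). Lce and Sprr2 genes lie in families of near-identical copies, so their separate values are uncertain.

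Matrix and mesenchymal genes and fibroblast markers rose with TGFb1. Of 33 extracellular matrix genes 26 rose and 1 fell (27 rose adjusted over the list alone), with a median of 4.11 and a list adjusted p = 5.76e-09 (adjusted p = 0.642 with an estimated correlation). Col7a1, which encodes a collagen of the basement membrane zone, rose from 61.4 ± 11.7 to 1078 ± 200 CPM and Tnc by 4.81 ± 0.30 (adjusted p = 0.000224 and 0.000274). Col1a1 was at 8.42 ± 6.61 and 1099 ± 811 CPM (adjusted p = 0.00305). Of 23 EMT and mesenchymal genes 12 rose and 1 fell (list adjusted p = 4.57e-05, adjusted p = 0.642 with an estimated correlation), and Vim rose by 3.70 ± 0.95 (adjusted p = 0.0232). Summed fibroblast markers went from 461 and 650 CPM in the control libraries to 1940 and 5610 CPM with TGFb1, and summed muscle markers from 19.3 and 98.6 to 95.3 and 389 CPM. The fibroblast sum includes matrix list genes, so it is not a separate measure of fibroblasts. The 14 fibroblast markers outside the matrix list had a median log2 fold change of 3.04 with a pseudocount of 0.1. Of 17 fibroblast markers 8 rose and 1 fell (list adjusted p = 0.00675, adjusted p = 0.786 with an estimated correlation), while 1 of 9 muscle markers rose and their list passed with the replicate block but not without it (adjusted p = 0.000264, against 0.115). In each group both sums were higher in replicate 2, with a median log2 ratio of 2.05 for muscle and 1.71 for fibroblast genes.

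Interferon-stimulated genes rose too, 12 of 19 with 0 falling (list adjusted p = 2.11e-05, adjusted p = 0.642 with an estimated correlation), among them Irf7 (3.90 ± 0.29) and Usp18 (2.48 ± 0.25). Of 34 ligands, receptors and antagonists of the BMP and TGFb pathways 15 rose and 2 fell (list adjusted p = 0.00508, adjusted p = 0.642 with an estimated correlation), including the ligand genes Tgfb2 (4.30 ± 0.36) and Tgfb3 (5.30 ± 0.36). Of 22 cytoskeleton genes 10 rose and 1 fell (list adjusted p = 0.0186, adjusted p = 0.642 with an estimated correlation). Of 22 cholesterol synthesis genes 13 fell and 2 rose (list adjusted p = 0.00508, adjusted p = 0.642 with an estimated correlation), with Lss falling by 1.09 on the log2 scale. Proliferation genes fell as a list (adjusted p = 0.0186, adjusted p = 0.786 with an estimated correlation), with 5 of 34 lower and 1 higher, but not without inhibitor replicate 1 (adjusted p = 0.118) or TGFb1 replicate 1 (adjusted p = 0.213). Mki67 did not pass (adjusted p = 0.319).

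Of 28 lists, 12 passed, against 13 with fry, which lost 3 of the 12, namely the proliferation, fibroblast and ribosomal lists (adjusted p = 0.304, 0.151 and 0.167). Ribosomal protein genes fell in 5 of 30 cases (list adjusted p = 0.000196, adjusted p = 0.786 with an estimated correlation). Mitochondrial transcripts held 0.455% and 0.631% of the TGFb1 libraries, against 0.657% and 0.684% in the control. The glycolysis and hypoxia list also passed downward (adjusted p = 0.0331), but not without inhibitor replicate 2 or TGFb1 replicate 2. In all, 3243 genes were higher and 3228 lower with TGFb1. Of 96 named calls, 79 held with each library left out, and Id1, Id3, Rptn and Vim were among those that lost theirs in at least 1 case. The named calls lost numbered 11 and 14 without inhibitor replicates 1 and 2, and 10 and 6 without TGFb1 replicates 1 and 2. The total was 3552 without inhibitor replicate 1, 3332 without inhibitor replicate 2, 3102 without TGFb1 replicate 1 and 4055 without TGFb1 replicate 2.

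Organoids given both ligands were then compared with the inhibitor group. TGFb and BMP response, matrix and tested columnar genes rose, and differentiation, sterol synthesis, cell cycle and ribosomal protein genes fell. Of 24 TGFb response genes 21 rose, and of 18 BMP response genes 12 rose and 1 fell (list adjusted p = 4.7e-09 and 0.00161, and adjusted p = 0.171 and 0.504 with an estimated correlation). Of 14 tested columnar genes 9 rose and 0 fell (list adjusted p = 0.000733, adjusted p = 0.504 with an estimated correlation). Id3 rose by 2.51 ± 0.33, Smad6 by 2.65 ± 0.25, Smad7 by 2.42 ± 0.21, Krt7 by 5.29 ± 0.39 and Sox9 by 2.59 ± 0.24 (adjusted p = 0.0017, 0.000489, 0.000401, 0.000257 and 0.000466). Krt4 fell by 3.14 and Krt13 by 1.30 on the log2 scale (adjusted p = 0.00058 and 0.00231). Of 38 suprabasal genes 26 fell and 4 rose (list adjusted p = 3.81e-09, adjusted p = 0.504 with an estimated correlation). Lgals7 fell from 307 ± 29.0 to 44.6 ± 5.20 CPM, and Sprr3, a cornified envelope gene, from 1634 ± 363 to 107 ± 25.3 CPM (adjusted p = 0.00021 and 0.000215).

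The largest falls were those of Rptn (-9.71 ± 1.76), Krtdap (-8.11 ± 1.20), Alox12b (-8.09 ± 0.60), Abca12, a lipid transporter gene of the skin barrier (1037 ± 220 to 3.15 ± 0.778 CPM), and Aloxe3 (-7.85 ± 0.71). The largest rises were those of Amtn, which encodes the enamel protein amelotin (9.26 ± 0.92), Lgr6, which encodes a receptor of R-spondins (9.12 ± 0.74), Adam12 (8.29 ± 0.14), the long noncoding RNA BC037156 (8.07 ± 0.87) and Eln (7.96 ± 0.85). Amtn averaged 724 ± 152 CPM and Lgr6 609 ± 153 CPM. Of 22 cholesterol synthesis genes 18 fell and 0 rose (list adjusted p = 3.81e-09, adjusted p = 0.504 with an estimated correlation). Of 34 proliferation genes 22 fell and 0 rose (list adjusted p = 2.12e-06, adjusted p = 0.546 with an estimated correlation), with Mki67 going from 60.4 ± 22.6 to 8.22 ± 8.94 CPM (adjusted p = 0.0315). Of 30 ribosomal protein genes 23 fell and 0 rose (list adjusted p = 9.61e-08, adjusted p = 0.546 with an estimated correlation). Mitochondrial transcripts, like ribosomal protein genes higher in replicate 2, held 0.366% and 0.628% of the libraries with both ligands, against 0.657% and 0.684% in the control. Matrix genes rose in 27 of 33 cases with 1 falling (list adjusted p = 4.62e-07, adjusted p = 0.546 with an estimated correlation). Beside them, summed fibroblast markers were at 2000 and 8000 CPM and summed muscle markers at 147 and 771 CPM, and these marker lists passed with the replicate block (adjusted p = 0.00247 and 0.000482) but not without it (adjusted p = 0.111 and 0.122). With median-of-ratios scaling the fibroblast list passed (adjusted p = 0.0278) and the muscle list did not (adjusted p = 0.0508). Cdh1 also passed with the block but not without it (adjusted p = 0.0457).

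Of 28 lists, 13 passed, against 16 with fry, which lost 2 of the 13, namely the proliferation and ribosomal lists (adjusted p = 0.0805 and 0.0703). In all, 4469 genes were higher and 2980 lower. The median of all tested genes was 0.13 above 0 on the log2 scale, as it was for BMP4 on top of TGFb1, and 0.12 for TGFb1 in the presence of BMP4. With median-of-ratios scaling that median was 0.01, and 3536 genes were higher and 3750 lower. Of 103 named calls, 87 held with each library left out, and Mki67 was among those that lost theirs in at least 1 case (adjusted p up to 0.143). The named calls lost numbered 9 and 13 without inhibitor replicates 1 and 2, and 6 and 7 without TGFb1 + BMP4 replicates 1 and 2. The total was 4493 without inhibitor replicate 1 and 4579 without inhibitor replicate 2.

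**Figure D2:**
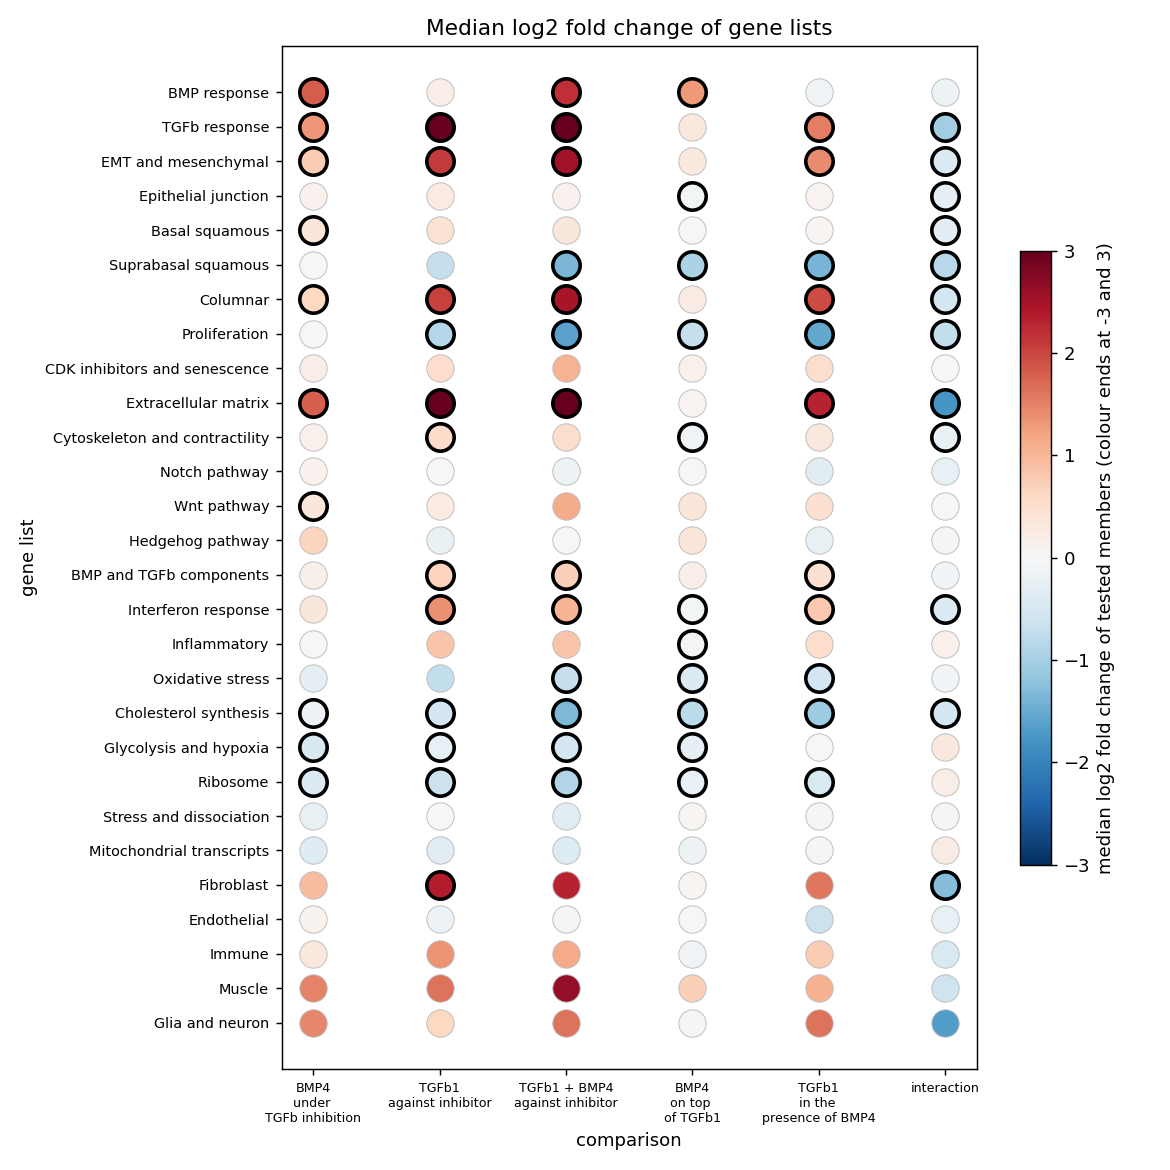
Median log2 fold change (colour) of the tested members of 28 gene lists (vertical axis) in 6 comparisons (horizontal axis), with a black outline where the list test passed an adjusted p of 0.05. TGFb response genes have medians of 3.28 and 3.16 in the groups with TGFb1 against the inhibitor, and suprabasal genes have a median of -1.38 with both ligands.

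BMP4 on top of TGFb1 was compared with TGFb1 alone. BMP targets rose and differentiation genes fell. Id3 went from 16.1 ± 7.31 to 306 ± 31.1 CPM, a log2 fold change of 4.23 ± 0.33 (adjusted p = 0.0108). Id1 rose by 2.35 ± 0.33, Smad6 by 2.36 ± 0.25 and Smad7 by 1.24 ± 0.21 (adjusted p = 0.0273, 0.013 and 0.0422), and Smad7 did not pass with median-of-ratios scaling (adjusted p = 0.0805). Of 18 BMP response genes 7 rose and 0 fell, with 12 rising when adjusted over the list alone (list adjusted p = 5.94e-09, adjusted p = 0.241 with an estimated correlation). Cdo1, a cysteine dioxygenase gene, rose from 5.50 ± 0.636 to 317 ± 70.4 CPM (adjusted p = 0.0126). Lgr6 rose by 4.34 ± 0.74, Cybrd1 by 3.91 ± 0.32 and C1qtnf3 by 3.34 ± 0.31. Krt4 fell from 4535 ± 940 to 391 ± 96.7 CPM (-3.54 ± 0.31, adjusted p = 0.0116) and Krt13 by 1.35 on the log2 scale (adjusted p = 0.0244). Of 38 suprabasal genes 12 fell and 0 rose (22 fell adjusted over the list alone), with a list adjusted p = 2.01e-25 (adjusted p = 0.241 with an estimated correlation). The largest falls were those of Lypd5 (-4.13 ± 0.58), the kallikrein genes Klk14 (-4.13 ± 0.65) and Klk8 (-3.97 ± 0.45), Alox12b (-3.99 ± 0.60) and Sprr2i (-3.86 ± 0.49). Krt7, Krt8, Krt18, Sox9, Cdkn2b, Vim and Mki67 did not pass.

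Cholesterol synthesis genes fell with BMP4, 9 of 22 with 0 rising (20 fell adjusted over the list alone), and the list adjusted p was 3.67e-22 (adjusted p = 0.241 with an estimated correlation). Dhcr7 went from 76.6 ± 1.52 to 31.8 ± 0.284 CPM (adjusted p = 0.0124). Proliferation genes had a median of -0.72 with 0 of 34 passing singly (list adjusted p = 3.37e-08, adjusted p = 0.688 with an estimated correlation). Of 22 oxidative stress genes 3 rose, namely Gclm, Gpx2 and Gclc, and 1 fell (list adjusted p = 5.76e-05, downward, adjusted p = 0.547 with an estimated correlation), while Gpx2 and Gclc did not pass with median-of-ratios scaling (adjusted p = 0.0698 and 0.0682). The interferon and inflammatory lists passed (adjusted p = 0.0488 and 0.0308) but not with median-of-ratios scaling (adjusted p = 0.144 and 0.155), nor with an estimated correlation (adjusted p = 0.703 and 0.688). Without TGFb1 replicate 1 their adjusted p was 0.53 and 0.865. The interferon list also missed it without TGFb1 + BMP4 replicate 1 (adjusted p = 0.207), and the inflammatory list without TGFb1 + BMP4 replicate 2 (adjusted p = 0.0918). The muscle list passed with the replicate block but not without it (adjusted p = 0.044, against 0.874).

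Of 28 lists, 11 passed, against 3 with fry, which lost 8 of the 11, namely the proliferation, oxidative stress, interferon, inflammatory, epithelial junction, cytoskeleton, glycolysis and ribosomal lists (adjusted p = 0.57, 0.395, 0.816, 0.57, 0.57, 0.467, 0.239 and 0.721). The junction call was also lost without TGFb1 replicate 1 or TGFb1 + BMP4 replicate 2, and the cytoskeleton call without TGFb1 replicate 1. In all, 149 genes were higher and 177 lower, against 100 and 250 with median-of-ratios scaling, 574 and 547 with the replicate block, 548 and 487 with the muscle marker level as a covariate and 37 and 43 with no filter. Of 34 named calls, 4 held with each library left out, among them Krt15, Sprr3 and C1qtnf3, and 14 were lost in every such case, including Smad7, Krt13, Lgr6, Gclm, Gpx2 and Gclc. Id3 and Krt4 each lost theirs in 1 case (adjusted p = 0.0545 and 0.064 at the highest). The named calls lost numbered 14 and 20 without TGFb1 replicates 1 and 2, and 30 and 28 without TGFb1 + BMP4 replicates 1 and 2. The total was 158 without TGFb1 replicate 1, 62 without TGFb1 replicate 2, 19 without TGFb1 + BMP4 replicate 1 and 26 without TGFb1 + BMP4 replicate 2, and limma on these 2 groups alone called 0 genes, with 3088 at an unadjusted p under 0.05.

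TGFb1 in the presence of BMP4 was compared with BMP4 and inhibitor. TGFb response genes rose in 19 of 24 cases with 0 falling (list adjusted p = 2.29e-07, adjusted p = 0.259 with an estimated correlation). Krt18 rose by 3.23 ± 0.26, Krt8 by 3.11 ± 0.31, Sox9 by 3.03 ± 0.24 and Krt7 by 2.48 ± 0.39 (adjusted p = 0.000677, 0.00122, 0.000616 and 0.00536). Trp63 fell by 0.72 and Mki67 by 3.85 on the log2 scale (adjusted p = 0.00538 and 0.0247). Id1, Id3 and Smad6 did not pass (adjusted p = 0.54, 0.671 and 0.414). Of 38 suprabasal genes 26 fell and 3 rose (list adjusted p = 2.48e-11, adjusted p = 0.765 with an estimated correlation), and the largest falls were those of Rptn (-9.89 ± 1.76), the desmoglein gene Dsg1a (860 ± 120 to 1.82 ± 0.106 CPM), Hrnr (-7.48 ± 0.31), Endou (-7.42 ± 0.91) and Klk14 (-7.26 ± 0.65). The largest rises were those of Amtn (7.35 ± 0.92), C1qtnf3 (6.93 ± 0.31), Alox15 (6.89 ± 0.27), BC037156 (6.77 ± 0.87) and Adam12 (6.48 ± 0.14). Proliferation genes fell in 17 of 34 cases and cholesterol synthesis genes in 17 of 22, with 0 rising in either list (list adjusted p = 7.92e-09 and 1.07e-09, and adjusted p = 0.765 and 0.628 with an estimated correlation). Matrix genes rose in 17 of 33 cases with 1 falling (list adjusted p = 0.000103, adjusted p = 0.765 with an estimated correlation), and the fibroblast and muscle lists passed with the replicate block but not without it (adjusted p = 0.00442 and 0.0064, against 0.34 and 0.492). Vim likewise passed with the block but not without it (adjusted p = 0.000854, against 0.131).

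Of 28 lists, 11 passed, against 8 with fry, which lost 5 of the 11, namely the proliferation, matrix, EMT, oxidative stress and ribosomal lists (adjusted p = 0.118, 0.0812, 0.0624, 0.183 and 0.339). In all, 2797 genes were higher and 1759 lower, against 1966 and 2122 with median-of-ratios scaling and 1315 and 1063 on the compared groups alone. Of 93 named calls, 77 held with each library left out, and Mki67 was among those that lost theirs in at least 1 case (adjusted p up to 0.0947). The named calls lost numbered 9 and 10 without BMP4 + inhibitor replicates 1 and 2, and 11 without either TGFb1 + BMP4 library. The total was 2674 without BMP4 + inhibitor replicate 2 and 2424 without TGFb1 + BMP4 replicate 2.

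Whether the BMP4 effect differed between inhibitor and TGFb1 was tested by the interaction of the 2 treatments. Added TGFb1 and the absent inhibitor cannot be told apart in this test. The effect on Krt10 was 6.79 ± 0.53 under inhibition and 0.75 ± 0.53 on top of TGFb1, an interaction of -6.04 ± 0.75 (adjusted p = 0.0313). Tgm7 (-5.34 ± 0.49), Frem2 (-5.63 ± 0.64), Stmn2 (-5.40 ± 0.51) and Dsg1a (-6.04 ± 0.98) were the other genes with the most negative interactions. Stmn2 was at 154 ± 1.94 CPM with TGFb1 alone and 227 ± 10.5 CPM with both ligands. The most positive were Serpinb12 (5.79 ± 0.95, adjusted p = 0.049, and 0.0504 with a stricter filter), Ccl20 (4.37 ± 0.41), Prkg2 (3.19 ± 0.49), C1qtnf3 (3.12 ± 0.44) and Wfdc18 (3.07 ± 0.34), and Wfdc18 went from 9.24 ± 1.20 to 91.0 ± 27.4 CPM when BMP4 joined TGFb1. Interactions of Id1, Id3, Smad6, Smad7, Krt4 and Krt13 did not pass (adjusted p = 0.309, 0.118, 0.996, 0.651, 0.477 and 0.352), and that of Id3 passed with the replicate block (adjusted p = 0.0452). In all, 48 genes had a positive and 160 a negative interaction, against 428 and 689 with the replicate block, 625 and 796 with the muscle marker level as a covariate, 7 and 20 with no filter and 1 and 12 with voom weights. Of the 10 named interactions 0 held by limma with each library left out, and 10 were lost without inhibitor replicate 1, inhibitor replicate 2 or either TGFb1 + BMP4 library, against 9 without BMP4 + inhibitor replicate 1 or TGFb1 replicate 2, 4 without TGFb1 replicate 1 and 1 without BMP4 + inhibitor replicate 2. The total from limma was 0 without inhibitor replicate 1, with 2690 at an unadjusted p under 0.05. It was 4 without inhibitor replicate 2, 5 without BMP4 + inhibitor replicate 1, 602 without BMP4 + inhibitor replicate 2, 93 without TGFb1 replicate 1, 4 without TGFb1 replicate 2, and 3 without either TGFb1 + BMP4 library.

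**Figure D3:**
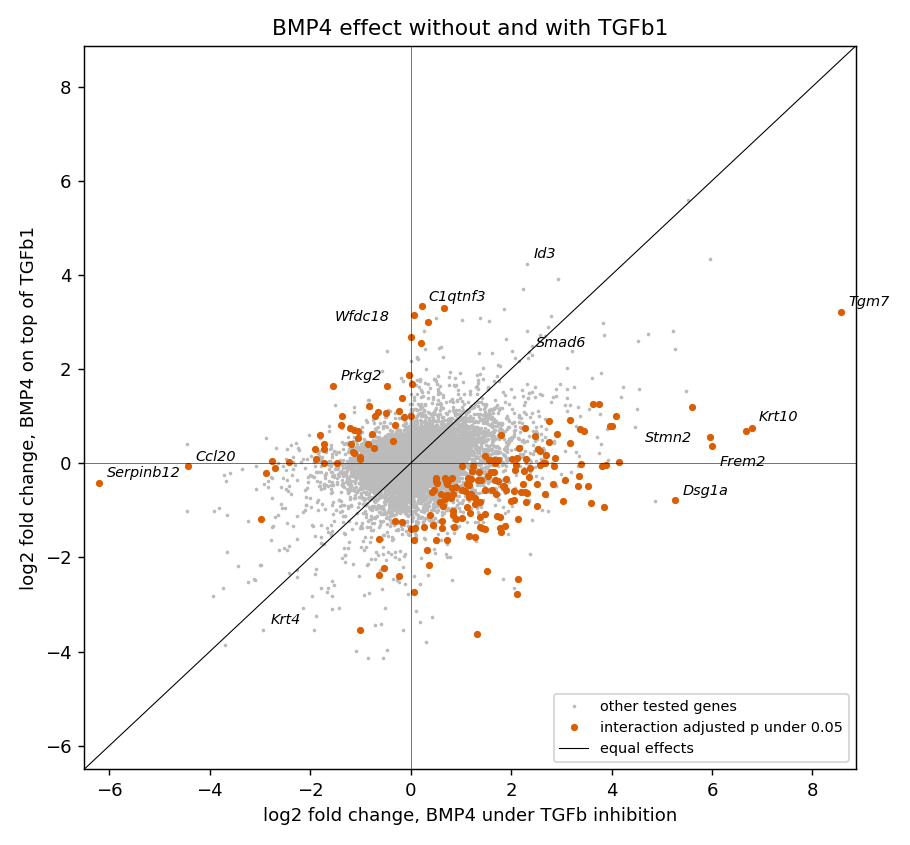
Log2 fold change of each of 16180 genes with BMP4 under TGFb inhibition (horizontal axis) and with BMP4 on top of TGFb1 (vertical axis), with genes past the interaction test in orange and a line of equal effects. Id3, at 2.31 and 4.23, and Krt4, at -2.94 and -3.54, lie on one side of 0 in both, while Krt10, at 6.79 and 0.75, lies far from the line.

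Across genes, which are not independent replicates, the BMP4 effects under inhibition and on top of TGFb1 had a Pearson correlation of 0.32 and a Spearman correlation of 0.28. These effects share no library. Of the genes called in both, 77 were higher in both, 48 lower in both and 14 opposite, against 8.2 and 5.2 for independent lists in the first 2 cases. That reference leaves out that both effects were tested with the same estimate of spread for each gene. The genes called in both in the same direction numbered 442 with the replicate block, 19 without inhibitor replicate 1, 16 without inhibitor replicate 2, 76 without BMP4 + inhibitor replicate 1, 57 without TGFb1 replicate 1, 28 without TGFb1 replicate 2, 6 without TGFb1 + BMP4 replicate 1 and 12 without TGFb1 + BMP4 replicate 2.

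The effects of BMP4 and of TGFb1 against their shared control had a Pearson correlation of 0.59 and a Spearman correlation of 0.62 across genes and a covariance of 0.446. Simulated unchanged groups with shared controls gave a median Pearson correlation of 0.50 and a median covariance of 0.043 over 100 draws, and the covariances differed by 0.403. Called in both were 538 genes higher, 307 lower and 89 in opposite directions, against 178.2 and 94.0 for independent lists, a value that leaves out the shared controls. In the simulated groups limma called a median of 0 genes and at most 1 gene in the same direction, a value that leaves out the effects, so neither measures a shared effect. The share of genes with the same sign was 74.4%, against a simulated 66.6%. A split of the 2 controls would leave 1 library per effect and was not run, so part of the overlap may come from the shared libraries. The genes in the same direction numbered 2417 with the replicate block, 153 without inhibitor replicate 1, 122 without inhibitor replicate 2, 221 without BMP4 + inhibitor replicate 1, 1679 without BMP4 + inhibitor replicate 2, 489 without TGFb1 replicate 1 and 513 without TGFb1 replicate 2.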

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

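The tests of the matrix and TGFb response patterns below were chosen after the results were seen, and that of the matrix members outside the basement membrane was changed after its first value was seen.

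The BMP4 effect differed between inhibitor and TGFb1 in 208 genes by the interaction test. Among the named genes the interaction, as a log2 value, was negative for Dsg1a (-6.04), Krt10 (-6.04), Frem2 (-5.63), Stmn2 (-5.40), Tgm7 (-5.34), Tnc (-3.62), Mal (-3.43), Gsta3 (-3.32), Igfbp3 (-3.22), Col7a1 (-2.96), Krt20 (-2.75), Sprr3 (-2.54), Tgfbi (-2.51), Bambi (-2.37), Dkk3 (-2.18), Id2 (-1.91), Cdkn2b (-1.84), Itgb6 (-1.53), Adam12 (-1.21) and Dhcr7 (-1.06). It was positive for Serpinb12 (5.79), Ccl20 (4.37), Prkg2 (3.19), C1qtnf3 (3.12), Wfdc18 (3.07), Gpx2 (1.75) and Gclm (1.55). Serpinb12 and Ccl20 were at or below 1.90 and 0.25 CPM in the TGFb1 libraries, so a further fall with BMP4 was hardly measurable there. The total was 0 without inhibitor replicate 1, by limma with 2690 at an unadjusted p under 0.05, and ranged up to 602 without BMP4 + inhibitor replicate 2.

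The interaction was negative for 12 gene lists, whose median log2 interactions were -1.78 (extracellular matrix), -1.30 (fibroblast), -1.04 (TGFb response), -0.84 (suprabasal), -0.74 (proliferation), -0.56 (columnar), -0.55 (cholesterol synthesis), -0.46 (interferon response), -0.43 (EMT and mesenchymal), -0.32 (basal), -0.30 (epithelial junction) and -0.23 (cytoskeleton). Beside these the median of all genes was 0.12. With an estimated correlation 0 of the 12 passed, the lowest adjusted p being 0.157 for TGFb response genes. With fry 1 of the 12 passed, that of TGFb response genes (adjusted p = 0.0302). The EMT and fibroblast lists each missed the threshold without inhibitor replicate 1 (adjusted p = 0.0882 and 0.0683), BMP4 + inhibitor replicate 2 (0.168 for both), TGFb1 replicate 2 (0.252 and 0.26) or TGFb1 + BMP4 replicate 1 (0.31 and 0.251). The interferon list missed it without BMP4 + inhibitor replicate 1 (0.0713), TGFb1 replicate 1 (0.083) or TGFb1 + BMP4 replicate 1 (0.0625). The junction list missed it without TGFb1 + BMP4 replicate 2 (0.0983), the proliferation list without TGFb1 replicate 2 (0.0882) and the cytoskeleton list without BMP4 + inhibitor replicate 2 (0.127).

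Matrix genes rose with TGFb1 beside higher sums of muscle and fibroblast markers, and the fibroblast sum includes matrix list genes. With the muscle marker level as a covariate 25 of the 26 raised members kept their call. Of all 6471 calls of this comparison 5934 were kept, so the kept calls do not decide on a larger share of muscle cells. The median log2 fold change of the raised members was 3.22 with the covariate against 4.74 before. In every group the muscle markers were higher in replicate 2, so the covariate cannot be told apart from the replicate number within groups. The value of 3.22 therefore does not decide on a larger share of muscle cells either. For the 7 basement membrane members the median log2 ratio of replicate 2 to replicate 1 was 0.09, below the lower quartile of 0.75 of 14 fibroblast markers, which argues against a larger share of fibroblasts for these as a set, with Col4a1 (2.11) and Col4a2 (2.01) as exceptions. For the 19 other members as a set a larger share of fibroblasts cannot be told apart from a change in expression, since their median log2 fold change of 5.64 (pseudocount 0.1) lay above the markers' upper quartile of 3.94 while their replicate ratio of 1.74 was as high as that of fibroblast markers. Exceptions were Tnc (0.31), Col12a1 (0.26), Plod2 (0.57) and P4ha2 (0.19), whose replicate ratios lay below the markers' lower quartile like those of most basement membrane members. Higher matrix expression within epithelial cells or within fibroblasts may each contribute, and neither was tested.

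TGFb response genes rose with BMP4 although the inhibitor was present. With either control library left out the list's highest adjusted p at the preset correlation was 3.42e-08, which argues against a chance low value in 1 control library. The list did not pass with an estimated correlation (adjusted p = 0.177, all libraries) and passed with fry (adjusted p = 0.00278). With the muscle marker level as a covariate 11 of 11 raised members kept their call. So did all 1360 calls of this comparison, so the kept calls do not decide on a larger share of muscle cells. The median log2 fold change of the raised members was 1.95 with the covariate against 2.16 before. This does not decide on it either, since within groups the covariate cannot be told apart from the replicate number. Both groups received the inhibitor at 500 nM, so an incomplete block of the receptors alone would not make them differ. A direct response to BMP4 cannot be told apart from TGFb signalling that BMP4 raised past an incomplete block, because the inhibitor was given at this dose only.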

How the results depend on the processing

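Voom weights, the muscle marker covariate, the block with median-of-ratios scaling and the block for overlaps were chosen after seeing the data. No called gene turned its direction in the settings where calls were compared, and no called list did. The balance of calls did turn, from 4469 higher and 2980 lower to 3536 and 3750 for TGFb1 + BMP4 against inhibitor and from 2797 and 1759 to 1966 and 2122 for TGFb1 in the presence of BMP4, both with median-of-ratios scaling. For BMP4 on top of TGFb1 it turned from 149 and 177 to 574 and 547 with the block, 548 and 487 with the muscle covariate, 13 and 6 without TGFb1 + BMP4 replicate 1 and 15 and 11 without TGFb1 + BMP4 replicate 2. With the muscle covariate it also turned from 889 and 471 to 1978 and 2139 for BMP4 under inhibition and from 3243 and 3228 to 3624 and 4202 for TGFb1 against inhibitor, the latter being 3045 and 3099 with voom weights. Counts of genes changed are given in the order BMP4 under inhibition, TGFb1 against inhibitor, TGFb1 + BMP4 against inhibitor, BMP4 on top of TGFb1, TGFb1 in the presence of BMP4 and interaction, with main values of 1360, 6471, 7449, 326, 4556 and 208. With the replicate block BMP4 under inhibition gave 3502, BMP4 on top of TGFb1 1121 and the interaction 1117, and all main calls remained in each comparison. With the block and median-of-ratios scaling these were 3567, 1114 and 1188, and with the muscle covariate 4117, 1035 and 1421. With no filter they were 751, 80 and 27, where more genes were tested. Fits of the compared groups alone gave 581 for BMP4 under inhibition, 2378 for TGFb1 in the presence of BMP4 and, for BMP4 on top of TGFb1, 0 from limma with 3088 at an unadjusted p under 0.05. An absolute log2 fold change over 1 left 835, 3065, 3832 and 2341 for BMP4 under inhibition, TGFb1 and TGFb1 + BMP4 against inhibitor, and TGFb1 in the presence of BMP4, by construction. Voom weights gave 13 interactions. Where not stated, the cause was not tested.

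With 1 library left out, and the lone library of its group assumed to vary like the others, the counts ranged from 188 to 2300, 3102 to 4055, 4493 to 5773, 19 to 158, 2424 to 3839 and 0 to 602. The genes called in both BMP4 effects, 125, ranged from 6 to 161 and were 442 with the replicate block. Those called in both BMP4 and TGFb1 against the shared control, 845, ranged from 122 to 1679 and were 2417 with the block. List calls, 69 in all, ranged from 63 to 74 and were 0 with an estimated correlation, 47 with fry (35 of the 69 passed and 34 were lost), 79 with the replicate block and 68 with median-of-ratios scaling. With a library left out, 37 tests of called lists and 377 tests of called named genes no longer passed, and 1267 of the latter did. Of 401 calls of named genes, 14 were lost with median-of-ratios scaling, 74 with no filter, 3 with the muscle covariate, 2 with the stricter filter and 0 with the replicate block. The block ended 1 list call, that of basal genes with BMP4 under inhibition (0.0631), and added 11, those of muscle markers in all 6 comparisons (0.000755 in the interaction), of fibroblast markers in 3 and of mitochondrial transcripts in 2 (0.0425 for BMP4 under inhibition and 0.0327 for both ligands against inhibitor). Fits with a library left out held no replicate block, and same-numbered libraries deviated together. Calls lost or gained in them may therefore come from unequal replicate numbers as well as from the missing library. The planned DESeq2 alternative was not run because the values are not counts. Depth limits statements on genes near 0.15 CPM.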

Other observations

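The tests of the chromosome 5 pattern below were chosen after the result was seen, and the permutation replaced a first comparison with a fixed grid of windows.

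Summed markers of glia and neurons were at 17.8 ± 1.84 CPM (SD, n = 2) in the inhibitor group and at 133 ± 2.02 with BMP4, 134 ± 9.54 with TGFb1 and 127 ± 54.3 with both. The glia list did not pass in any comparison by camera (lowest adjusted p = 0.0824). With fry, which does not compare a list with other genes, it passed for BMP4 under inhibition, TGFb1 and both ligands against inhibitor (adjusted p = 0.0451, 0.045 and 0.00745). Summed intestinal markers were at 4.42 ± 1.02, 22.6 ± 4.21, 340 ± 13.9 and 465 ± 99.2 CPM in these groups, and only 3 of the 22 members were tested, with Krt20 at 324 and 334 CPM in the TGFb1 libraries. The intestinal regulators Cdx1 and Cdx2 were listed at 0 in every library. Summed immune markers were at 176 ± 13.5, 141 ± 20.9, 346 ± 6.67 and 321 ± 18.9 CPM, endothelial markers at 30.1 ± 6.71, 40.2 ± 17.7, 27.0 ± 15.5 and 32.4 ± 23.1 CPM, and airway markers at 42.2 ± 1.63, 36.5 ± 16.0, 12.9 ± 2.86 and 17.2 ± 2.08 CPM.

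Neighbouring genes on chromosome 5 rose in the groups with TGFb1. Within 1 Mb, 5 of 6 tested genes were called with a log2 fold change over 4 in TGFb1 + BMP4 against the inhibitor, namely Odam (7.12), 1700066N21Rik (6.83), BC037156 (8.07), Csn3 (6.03) and Amtn (9.26). With TGFb1 alone their log2 fold changes were 4.05, 5.19, 6.45, 4.24 and 6.62, and all 5 were called. Their further change with BMP4 on top of TGFb1 did not pass (adjusted p = 0.142 to 0.356), and with the replicate block it passed for Odam and Csn3 (adjusted p = 0.038 and 0.0472) and for 1700066N21Rik, with an adjusted p under 0.05. They were singled out after their values were seen. Reads shared between overlapping genes are argued against as the whole cause, since 2 of the 5, Odam (87885029 to 87894174) and Amtn (88376108 to 88385916), overlap none of the others. In 33 of 1000 permutations of the 189 such genes over the tested positions a window of 1 Mb held as many, and the highest number elsewhere was 4. The permutation counts each gene as a separate position, although 1700066N21Rik overlaps both BC037156 and Csn3 and may share reads with them. It therefore does not decide whether the neighbourhood responds together. Such a neighbourhood may be a hypothesis to follow, and it was found and tested on the same data.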
